A study of Homo sapiens with 27 samples.

How the data were processed

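RNA from U937 cells was labelled in 27 samples (2.5 µg each) and read on a one-colour Phalanx Human OneArray, per the labels. The deposited table holds linear spot intensity values, 1 per probe and array, and the scanner, the background correction and the scaling are not given in the sources used here. Values in an array are whole steps times 1 factor (0.902 to 1.20 between arrays), and some lie below 0, so background was subtracted before deposit. No per-sample column was left unused. The arrays' log2 medians differed by more than the limit set for leaving a table as it is, from 5.37 to 6.65, so intensities were floored at 1, log2 transformed and quantile normalised over the 27 arrays. On an array 4.35% to 7.59% of values were floored. The mean log2 median was 0.479 higher with LPS and 0.321 higher with PBD150 plus LPS than untreated, a difference that quantile normalisation removes. Part of it came from 1 culture. Untreated replicate 1 had array medians of 5.37 to 5.55, against 6.12 to 6.23 in untreated replicates 2 and 3.

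The 3 arrays of a biological replicate were averaged on the log2 scale, giving 9 values per probe. The labels call the replicates biological, and they were used as such. Their differences exceeded those between technical arrays in every pair (median variance ratio 0.821 to 4.35, 0.549 with no difference), which does not show that the cultures were independent. Tests used limma 3.58.1 in R 4.3.3, with a group-means model over all 9 replicates, moderated variances, two-sided tests and Benjamini-Hochberg adjustment over 30968 probes at 0.05. No replicate block was used, since the numbers are not known to mark a shared day. The groups share 1 spread per probe, although the median SD between replicates was 0.104 untreated, 0.263 with LPS and 0.271 with PBD150 plus LPS.

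Gene lists were tested with camera at a preset inter-gene correlation and again with an estimated one, adjusted over 120 tests (40 lists in 3 comparisons). Of the 41 lists 1 had fewer than 5 measured genes and was counted only. Of 25 lists past the threshold for LPS against untreated, 4 held with an estimated correlation, as did 3 of 25 for PBD150 plus LPS against untreated and 0 of 4 for PBD150 plus LPS against LPS. The PBD150 effect on LPS-changed genes used LPS replicates held out of the call, since both comparisons share the LPS arrays with opposite sign.

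Symbols came from the platform's probe table, updated by name through RefSeq genes of GRCh38.p14. Of the 30968 probes 17397 had 1 symbol, 0 had several and 13571 were unnamed here. 14670 symbols were current, 2645 were updated from older ones and 82 stayed unmatched. A gene was represented by its brightest probe, 15207 genes in all, and CCL7 and CCL13 had no named probe. The groups, tests, lists and named-gene rule were fixed before the data were examined. In each comparison the text may name QPCT, QPCTL, CCL2, CCL7, CCL8, CCL13 and CX3CL1, the 8 largest rises and falls that passed without overlap of replicates and with a mean in the higher group at or above the median probe, and up to 4 genes of each list with the smallest p. Where fewer than 5 passed in a direction, the 5 genes with the largest moderated statistic are named as not past the threshold.

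The noise limit of an array was 3 times the root mean square of its values below 0. A gene not above it on any array of a group, or within 99% of the array maximum on all of them, has only a bound there. "At least N-fold" then sets the bright group's mean against the dim group's, with values under the limit raised to it. These probes made up 10.4% to 11.0% of a group at the noise limit, and 17 to 37 probes at the top.

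The tests were tried on simulated data, first with each probe's own spread in each group and then, after those results were seen, with 2 milder forms, with 100 probes changed by each size among 30968. With 1 spread for all groups, PBD150 plus LPS against LPS recovered 84% of 4-fold and 4% of 2-fold changes, and 6.38% of calls were false. LPS against untreated recovered 87% and 3%, with 7.22% false. With each group at its own median spread, PBD150 plus LPS against LPS recovered 83% and 16% with 22.7% false, and LPS against untreated 79% and 2% with 1.22% false. With each probe's own spread in each group the figures were 76%, 28% and 28.8%, and 79%, 33% and 18.8%, so false calls exceeded the nominal 5% in all but 1 of the 6 runs. The real data gave no call in the comparison where this was largest. In LPS against untreated the simulated runs had 82 to 138 calls, against 6956 in the real data, 5289 of them at least 2-fold. An adjusted threshold is looser in p where more probes change, so these recovered and false shares do not describe the real LPS comparison. A simulated list shifted by -0.5 passed and 0 of 40 unshifted lists did, but simulated genes are independent and had 1 spread for all groups there. A held-out estimate of -0.288 stood against a true -0.264 with 20% of the LPS change removed.

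Alternatives covered the scaling, technical averaging, dim probes, the pseudocount (16), the groups fitted, the variance prior, the threshold, the replicate block and each replicate left out. Array weights, a later floor, median centring for lists, lists without each replicate and the fits with no untreated array shared were added after seeing the data.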

Results

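Gene expression was measured in U937 cells, an established human line of monocyte-like cells, with a one-colour oligonucleotide array read in the Cy5 channel. The 3 groups were untreated cells, cells given lipopolysaccharide (LPS, a bacterial wall component that activates Toll-like receptor 4) at 4 µg/ml, and cells given LPS after 2 h with 10 µM PBD150. PBD150 is an inhibitor of glutaminyl cyclase (QC), the enzyme activity that turns an N-terminal glutamine into pyroglutamate on several CC chemokines. Cells were cultured for 48 h. The labels call the cells macrophages and name no differentiating agent, so how far untreated cells had differentiated is not known here. Each group had 3 biological replicates with 3 arrays each, 27 arrays in all, and n = 3 below counts biological replicates. Array medians lay between 41.5 and 100.3 intensity units, and 69.0% to 77.8% of the 30968 probes on an array were above its noise limit.

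The first comparison asked what LPS changed. MMP9, a gelatinase that cuts extracellular matrix, rose by 9.55 ± 0.31 (log2, SE) and SPP1, which encodes osteopontin, by 8.98 ± 0.22. PLK1, a mitotic kinase, was at -2.73 ± 0.16 and NOLC1, a nucleolar protein, at -3.14 ± 0.15, and both fell. Of 30968 probes, 3292 were higher and 3664 were lower at an adjusted p under 0.05 (limma), and the smallest adjusted p was 5.46e-07.

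Among the matrix metalloproteinases and their inhibitors, 13 of 19 measured genes rose and none of the 19 fell (camera adjusted p = 1.29e-08, adjusted p = 0.0314 with an estimated correlation). MMP1, a collagenase, rose by 7.37, PLAUR, the urokinase receptor, by 4.05 and TIMP1, a metalloproteinase inhibitor, by 2.84. Of 23 macrophage differentiation markers, 14 rose (adjusted p = 1.72e-08, adjusted p = 0.0694 with an estimated correlation). CD14, the LPS co-receptor, was near the scanner limit with LPS and so rose at least 121-fold. ADGRE1, the human F4/80 homologue, rose by 6.20 and TYROBP, a signalling adaptor of myeloid receptors, by 4.40. Of 13 S100 proteins and myeloid alarmins, 9 rose and 1 fell (adjusted p = 2.76e-05, adjusted p = 0.0694 with an estimated correlation). S100A9 rose at least 68.6-fold and S100A12 by 6.65, while S100A8 rose by 7.13 with an SD of 2.42 between the LPS replicates.

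Of 19 NF-kB feedback genes and targets, 13 rose (adjusted p = 8.94e-07, adjusted p = 0.141 with an estimated correlation), among them TNFAIP3, a deubiquitinase that restrains NF-kB, by 3.40 and ICAM1, an adhesion molecule, by 3.68. Of 15 inflammatory cytokines, 8 rose and 2 fell (adjusted p = 0.00468, adjusted p = 0.136 with an estimated correlation). IL1B rose at least 51.1-fold and OSM, which encodes oncostatin M, by 6.01. Of 10 CC chemokines, 6 rose (adjusted p = 0.000221, adjusted p = 0.136 with an estimated correlation), with CCL3 at 6.67 and CCL20 at 2.94. Of 30 interferon-stimulated genes, 16 rose (adjusted p = 1.72e-08, adjusted p = 0.109 with an estimated correlation), with ISG15 at 4.46 and IFIT1 at 3.60. Of 18 p53 targets and arrest genes, 11 rose (adjusted p = 2.64e-05, adjusted p = 0.0429 with an estimated correlation), with CDKN1A, the cyclin-dependent kinase inhibitor p21, at 5.06.

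Most measured genes of ribosome biogenesis, DNA replication and mitosis fell. All 17 measured MYC targets and ribosome biogenesis genes fell (adjusted p = 1.68e-12, adjusted p = 0.0314 with an estimated correlation), NCL, which encodes nucleolin, by -2.67 and LYAR by -3.15. Of 33 DNA replication genes, 28 fell (adjusted p = 4.96e-14, adjusted p = 0.109 with an estimated correlation), with MCM4, a subunit of the replicative helicase, at -3.24. Of 24 mitosis genes, 23 fell (adjusted p = 7.41e-14, adjusted p = 0.136 with an estimated correlation), with MKI67 at -2.54 and CCNA2, cyclin A2, at -3.32. The heat shock genes had 5 of 9 lower and 1 higher (adjusted p = 0.0109, adjusted p = 0.23 with an estimated correlation), led by HSPD1, the mitochondrial chaperonin, at -4.54. Of 24 oxidative phosphorylation genes 8 fell (adjusted p = 0.00957, adjusted p = 0.234 with an estimated correlation), with SDHB, a subunit of complex II, at -1.34, and this list did not pass on the values as deposited. Granulocyte markers did not move as a group, with 4 of 11 lower and 2 higher (adjusted p = 0.703). PRTN3, the granule protease proteinase 3, was at -3.63 and CAMP, an antimicrobial peptide precursor, at 3.23. Markers of other cell types also passed: 4 of 16 T or NK lymphocyte markers rose (adjusted p = 0.0133, adjusted p = 0.17 with an estimated correlation), with GZMB, a cytotoxic protease, at 5.80. Of 10 fibroblast or epithelium markers 3 rose (adjusted p = 0.0441, adjusted p = 0.176 with an estimated correlation), with EPCAM at 2.36.

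Of the QC enzymes and their chemokine substrates, 5 genes were measured. CCL8 rose by 3.76 ± 0.48 (adjusted p = 0.000823) and CCL2 by 2.29 ± 0.32 (adjusted p = 0.00124). QPCTL, the Golgi form of the enzyme, fell by 1.42 on the log2 scale (SE 0.30, adjusted p = 0.0107). That call was lost on the values as deposited, where the change was -1.06 with adjusted p = 0.0759. QPCT, the secreted form, differed by 0.56 (adjusted p = 0.46) and CX3CL1 by -0.07 (adjusted p = 0.911), and neither passed. Leaving out 1 replicate gave 0.17 to 0.96 for QPCT and -0.32 to 0.21 for CX3CL1. A pseudocount of 16 gave 0.13 and -0.02. For QPCTL it gave -0.96 (limma adjusted p = 0.00579), so the size of that fall depends on how dim values are handled. Without quantile normalisation the calls were 5935 higher and 2205 lower, and the median of all genes was 0.38 rather than 0.05. Median centring tilted the other way, with 2279 higher, 3806 lower and a median of -0.10, so the balance of rises and falls depends on the scaling.

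**Figure D1:**
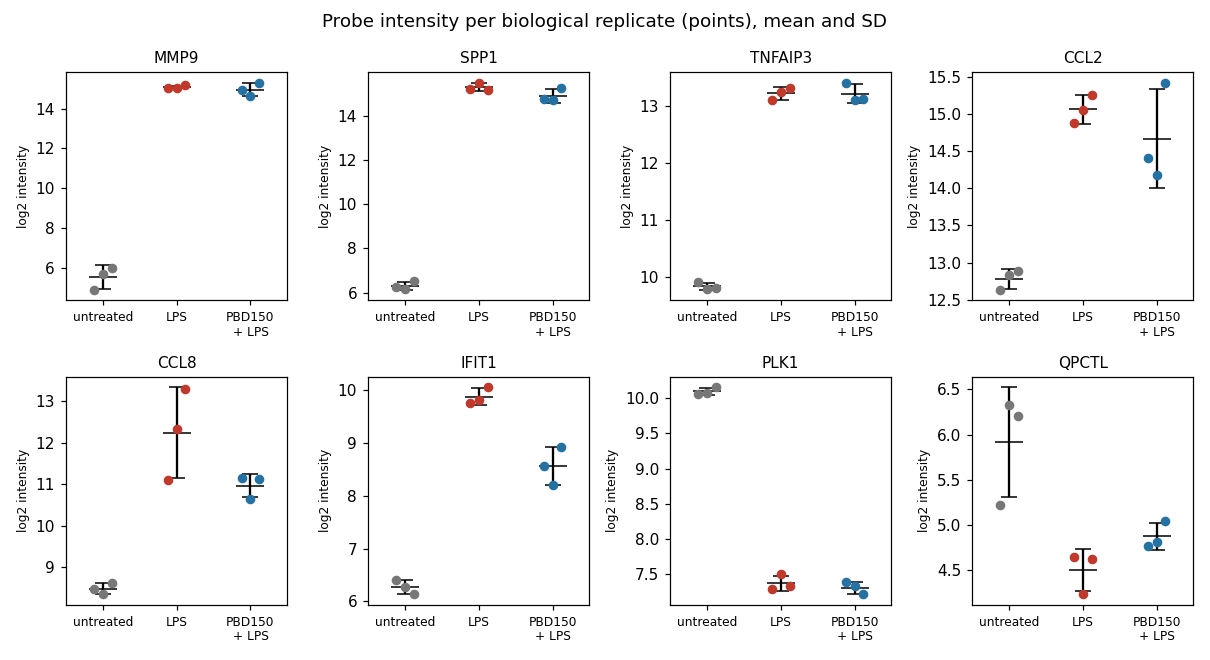
Log2 intensity (vertical axis) of 8 genes in the 3 groups (horizontal axis); each point is 1 biological replicate, and bars give the mean and SD (n = 3). MMP9, SPP1 and TNFAIP3 stand higher and PLK1 lower in both LPS groups. The CCL8 points with LPS and the CCL2 points with PBD150 plus LPS spread widely.

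The second comparison, the one the study's title names, asked what PBD150 changed in LPS-treated cells. No probe passed: limma gave 0 higher and 0 lower of 30968, with a smallest adjusted p of 0.414. At an unadjusted p under 0.05 there were 633 higher and 949 lower, 1582 in all, where chance alone gives about 1548. That count depended on single cultures and weights, with 1867 higher and 1909 lower without PBD150 plus LPS replicate 3 and 1068 and 1561 with array weights. Replicate groups did not overlap for 7.98% of probes, where chance gives 10%. With all 27 arrays and a random block for each culture, 1 probe was higher (HIPK2) and 13 were lower, among them IFIT1 (adjusted p = 0.000252). That fit assumed 1 correlation of 0.239 between arrays of a culture for all probes and groups. Cultures differed more in the 2 LPS-treated groups (median SD 0.263 and 0.271) than untreated (0.104), so its p-values may be too small here.

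The chemokines that QC modifies had the following values. CCL8 differed by -1.27 ± 0.48 (log2, SE, adjusted p = 0.906) and CCL2 by -0.39 ± 0.32 (adjusted p = 0.906). Single cultures moved both: leaving out 1 replicate gave -1.84 to -0.75 for CCL8 and -0.77 to -0.15 for CCL2. For CX3CL1 the difference was 0.23 ± 0.31, for QPCT 0.60 ± 0.48 and for QPCTL 0.38 ± 0.30, each with adjusted p = 0.906. With 1 LPS-treated replicate left out, these ran from -0.04 to 0.48, 0.34 to 0.98 and 0.24 to 0.45, so the sign for CX3CL1 turned. A pseudocount of 16 gave 0.08, 0.29 and 0.19. None of 10 CC chemokines, 15 inflammatory cytokines, 19 NF-kB genes, 19 metalloproteinase genes or 23 macrophage markers passed. Their median differences were 0.18, -0.01, -0.12, 0.11 and 0.07.

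Interferon-stimulated genes had lower values with PBD150, with 27 of 30 below 0 and a median of -0.41. No member passed over all probes, and 4 were lower when adjusted over the list alone. These were IFIT1 (-1.31 ± 0.22, adjusted p = 0.414), IFIT3 (-1.08 ± 0.28), IFIH1, an RNA sensor (-0.77 ± 0.19), and MX2 (-0.57 ± 0.16). The list passed camera with a preset correlation (adjusted p = 7.15e-07) and not otherwise (adjusted p = 0.136 with an estimated correlation). For the 17 MYC targets and ribosome biogenesis genes the median was -0.42 (adjusted p = 5.19e-07, adjusted p = 0.0659 with an estimated correlation). Their replicate medians from the untreated mean did not overlap, at -2.51 to -2.22 with LPS and -3.01 to -2.68 with PBD150 plus LPS. Medians of the intensity itself did overlap (9.03 to 9.55 and 8.86 to 9.12). In 7 of the 17 genes all PBD150 plus LPS values lay below all LPS values, and in 0 above. DNA replication genes had a median of -0.25 (adjusted p = 0.0015, adjusted p = 0.355 with an estimated correlation) and mitosis genes one of -0.27 (adjusted p = 0.00947, adjusted p = 0.573 with an estimated correlation). Neither of the latter passed without LPS replicate 1 (adjusted p = 0.266 for DNA replication and 0.777 for mitosis), without PBD150 plus LPS replicate 3 (0.0556 and 0.375) or with array weights (0.0536 and 0.556). As a count, 4 lists is no more than regroupings of the same cultures gave. Of the 10 splits of the 6 LPS-treated replicates, the real one included, 5 had 4 or more and 1 had 7. A count does not judge single lists. For interferon-stimulated genes the real split had the smallest camera p (preset correlation, 7.74e-08, next 4.56e-06), though 10 splits cannot give a share under 0.1. The other lists were not compared singly over the splits.

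The largest test statistics among named genes were those of LIM2 (-1.55 ± 0.20), PEAK3 (-1.24 ± 0.17), SLC25A27 (-1.96 ± 0.29), TMEM98 (-1.28 ± 0.19) and ADAM22 (-1.53 ± 0.24), each with adjusted p = 0.414. In the other direction they were those of LINC01587 (1.21 ± 0.25, adjusted p = 0.62, another probe 0.33), HIPK2, a stress-activated kinase (0.99 ± 0.24, adjusted p = 0.677), KRTAP1-5 (0.78 ± 0.20), NPY6R (0.73 ± 0.19) and FABP6 (0.68 ± 0.19, adjusted p = 0.858). A missed threshold does not show equal expression. Of the 15484 brighter probes, 77.6% had a 95% interval that excluded a doubling or halving and 98.8% one that excluded a 4-fold change. Those intervals use the spread shared with untreated cells (median SD 0.104, against 0.263 and 0.271 in the 2 groups compared), so many may be too narrow.

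For genes that LPS changed, the further difference with PBD150 was measured against an LPS replicate left out of the call. Signed by the LPS direction its median was 0.303, 0.0962 and 0.0482 with LPS replicates 1, 2 and 3 held out, a mean of 0.149, or 0.0334 on the values as deposited. Positive values mean a larger LPS change with PBD150 than in the held-out LPS replicate. LPS replicate 1, with the largest value, itself kept 85.9% of the rise and 70.8% of the fall of these genes. That value therefore cannot be told apart from a weaker response in that culture. LPS-lowered genes carried most of the difference, with medians of -0.477, -0.163 and -0.0884, while LPS-raised genes had 0.148, 0.0143 and 0.014.

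**Figure D2:**
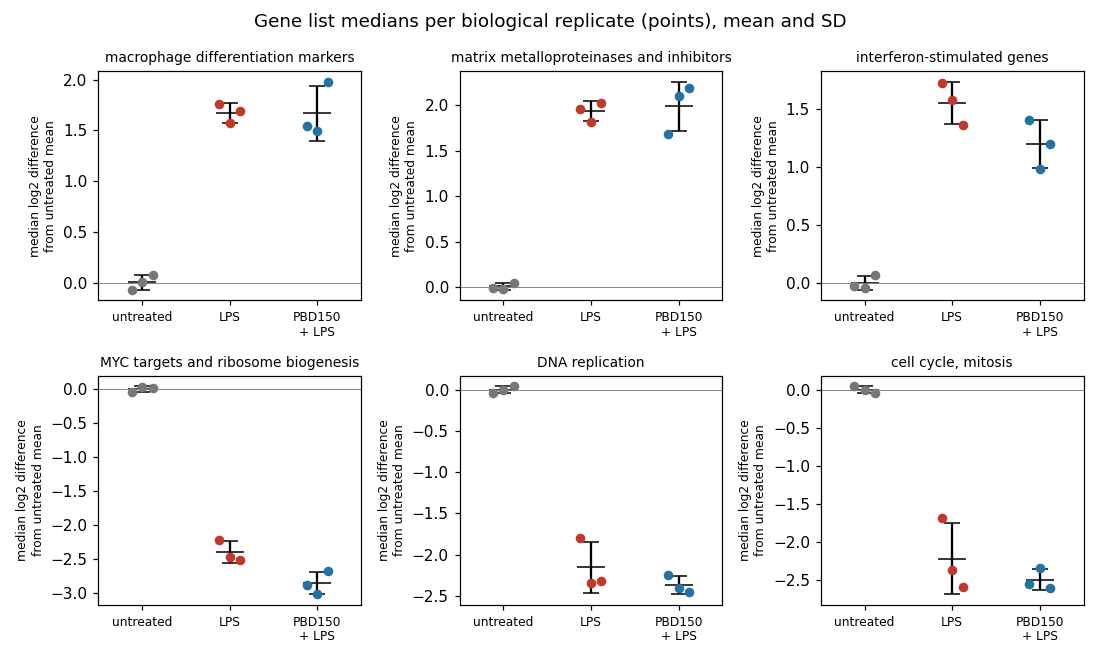
Median log2 difference from the untreated mean (vertical axis) for 6 gene lists in the 3 groups (horizontal axis); each point is 1 biological replicate, and bars give the mean and SD (n = 3). Interferon-stimulated gene medians were 1.36 to 1.72 with LPS and 0.985 to 1.40 with PBD150 plus LPS, so the groups overlapped. Those of MYC targets and ribosome biogenesis were -2.51 to -2.22 and -3.01 to -2.68, without overlap.

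The third comparison set PBD150 plus LPS against untreated cells. MMP9 rose by 9.41 ± 0.31, SPP1 by 8.60 ± 0.22 and TDO2, the tryptophan-degrading dioxygenase, by 7.50 ± 0.22. HMGB2, a chromatin protein of dividing cells, was at -6.65 ± 0.60 and MYC, a growth-promoting transcription factor, at -5.14 ± 0.45, and both fell. In all, 3887 probes were higher and 4174 lower (limma, smallest adjusted p 7.17e-07), and on the values as deposited 5051 were higher and 3069 lower. CCL2 rose by 1.89 (adjusted p = 0.0028) and CCL8 by 2.49 (adjusted p = 0.00555). QPCTL was at -1.05 (adjusted p = 0.0354). That call was lost under 8 alternatives, with adjusted p from 0.0503 without LPS replicate 3 to 0.156 on the values as deposited, and without untreated replicate 2 it was 0.125.

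Of 19 metalloproteinase genes 15 rose (adjusted p = 1.72e-08, adjusted p = 0.0314 with an estimated correlation), and of 30 interferon-stimulated genes 14 rose and 1 fell (adjusted p = 2.4e-05, adjusted p = 0.144 with an estimated correlation). All 17 MYC targets and ribosome biogenesis genes fell (adjusted p = 1.19e-12, adjusted p = 0.0314 with an estimated correlation). Both treated groups shared 2814 higher and 3251 lower probes, with 0 called in opposite directions. Independent lists of those sizes share 413.2 and 493.8, a value that leaves out the shared untreated arrays, and simulated groups without effects shared 0, a value that leaves out the effects. The fold changes had a covariance of 1.03 and a correlation of 0.909, against 0.0816 and 0.497 simulated from the shared arrays alone. With no untreated array shared, 1 replicate serving one comparison and 2 the other, covariances were 0.931 to 0.962 and correlations 0.742 to 0.79. The fold changes thus stayed correlated without shared untreated arrays. Calls from fits with 1 untreated replicate are not used here, since that group then has no spread of its own. How far the shared arrays add to the overlap of calls is therefore not settled.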

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

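Array weights, the floor after scaling, median centring and left-out replicates for lists, single held-out replicates, fits with no untreated array shared and the 9 label exchanges were chosen after seeing the data. No direction of a named result that passed was reversed under the alternatives run. Calls for LPS against untreated moved as deposited (5935 higher, 2205 lower) and with array weights (5458 and 5552). Without 1 replicate they ranged from 2256 to 3724 higher and 2415 to 4160 lower, lowest without untreated replicate 2. For PBD150 plus LPS against untreated, array weights gave 6373 higher, and left-out replicates 2597 to 5051 higher and 2964 to 4805 lower. PBD150 plus LPS against LPS had 0 calls (limma) under each alternative but 1. All 27 arrays with a random block gave 1 higher and 13 lower, among them IFIT1, IFIT3, IFIH1 and MX2, in a fit whose p-values may be too small. Left-out replicates gave 0 and 0, with up to 1867 higher and 1909 lower at an unadjusted p under 0.05 without PBD150 plus LPS replicate 3. An estimated correlation left 3 lists higher and 1 lower for LPS against untreated, 2 and 1 for PBD150 plus LPS against untreated, and 0 lower for PBD150 plus LPS against LPS; 11 lists were higher in the second of these without the dimmest probes. In PBD150 plus LPS against LPS the list medians stay as they are with an estimated correlation, -0.414 for interferon-stimulated genes, -0.417 for MYC targets and ribosome biogenesis, -0.247 for DNA replication and -0.265 for mitosis, and none passes. With array weights DNA replication (adjusted p = 0.0536) and mitosis (adjusted p = 0.556) did not pass camera. Left-out replicates gave -0.638 to -0.308 for interferon-stimulated genes, -0.547 to -0.35 for MYC targets and ribosome biogenesis, -0.377 to -0.11 for DNA replication and -0.501 to -0.0542 for mitosis. DNA replication lost its call without LPS replicate 1 or PBD150 plus LPS replicate 3 (adjusted p = 0.266 and 0.0556), as did mitosis (0.777 and 0.375). LPS replicate 1 held out alone gave 0.303 for the PBD150 effect on LPS-changed genes, and the other settings 0.0334 (as deposited) to 0.166. The cause of these shifts was not tested. Between replicates of the same number the deviations correlated from -0.51 to 0.118. No clear positive correlation was seen, but with 3 replicates per group these values cannot exclude pairing by number or a shared day. With a replicate block LPS against untreated had 2508 higher and 2897 lower, and PBD150 plus LPS against untreated 2895 and 3433. PBD150 plus LPS against LPS had 0 and 0 there, with 4 lists lower. Probes near the noise limit have only bounds.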

Other observations

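In LPS against untreated, further lists passed. Of 21 lysosome genes 13 rose (adjusted p = 4.27e-05, adjusted p = 0.144 with an estimated correlation), with CTSB, the protease cathepsin B, at 2.76. Of 13 complement genes 7 rose (adjusted p = 0.00485, adjusted p = 0.11 with an estimated correlation), with C3 at 6.74 and CFD, complement factor D, at 3.15. Of 24 proteasome genes 13 fell and 1 rose (adjusted p = 0.000623, adjusted p = 0.144 with an estimated correlation), and PSMA7 was at -1.15, with a second probe at -0.68 that did not pass. Ribosomal protein genes had 7 of 12 lower (adjusted p = 0.000337, adjusted p = 0.195 with an estimated correlation), with RPS14 at -1.51. The 19 genes of alternative activation had 12 higher (adjusted p = 8.8e-06, adjusted p = 0.0429 with an estimated correlation), among them IL1RN, the interleukin-1 receptor antagonist, at 4.31. ABCA1, the cholesterol exporter, rose by 5.07.

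In the pattern of lower interferon-stimulated genes with PBD150 plus LPS, the tests of a weaker overall LPS response and of other splits were chosen after related values were seen. Left-out replicates and median centring for lists were also added after seeing the data. LPS-raised genes outside the list lost -5.07% of their rise on average, that is, they gained. The values were -12.8%, -1.3% and -1.12% with LPS replicates 1, 2 and 3 held out, so the gain came mostly with LPS replicate 1. The 15 to 20 of 30 list members called raised lost 33% (12.2%, 42.3% and 44.3% in the same order). This argues against a weaker response of all LPS-raised genes. With other scalings the list median minus that of all genes was -0.393 at its weakest (-0.408 with quantile normalisation), against the scaling as the whole source. Leaving out any 1 of the 6 LPS-treated replicates gave list medians of -0.638 to -0.308 and an adjusted camera p (preset correlation) of at most 0.00103. Other splits of the same cultures reached 0.00149, 0.00128 and 3.22e-05, so a p of that size cannot exclude 1 culture as the source. Chance stays open: the camera p was 7.74e-08, the smallest other split gave 4.56e-06, and 10 splits cannot give a share under 0.1, with 1 split as small. An effect of PBD150 on these genes is a hypothesis that these data leave open. No gene passed over all probes with averaged arrays, and the list call ends with an estimated correlation. With all 27 arrays and a random block 4 passed, but the p-values of that fit may be too small.

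LPS replicate 1 stood apart from LPS replicates 2 and 3, every test of this was chosen after it was seen, and all 3 of its arrays correlated less with those replicates than their arrays did with each other, which argues against 1 poor array. It kept 85.9% of the rise and 70.8% of the fall of LPS-changed genes, as a weaker response in that culture would give. Not every list median was lower there: interferon-stimulated genes had 1.72 (1.58 and 1.36 in LPS replicates 2 and 3) and NF-kB targets 2.17 (1.54 and 2.06). The interferon-stimulated members called raised without the held-out replicate went the other way. For them PBD150 plus LPS differed by a median of -0.16 from LPS replicate 1, and by -0.626 and -0.694 from replicates 2 and 3. Whether the interferon-stimulated response was weaker in LPS replicate 1 is thus not settled. Exchanging its label with that of PBD150 plus LPS replicate 1 changed the variance within groups by -14.1%, but exchanging PBD150 plus LPS replicate 3 with LPS replicate 3 or 2 changed it by -24% and -15.2%, so this test is not specific to LPS replicate 1 and an exchange stays open. The closest to LPS replicate 1 was PBD150 plus LPS replicate 3 (SD of log2 differences 0.561, against 0.663 and 0.709 within LPS). PBD150 plus LPS replicate 3 also lay nearer LPS replicates 2 and 3 (0.393 and 0.449) than its own group (0.603 and 0.581). PBD150 plus LPS replicate 1 lay nearer LPS replicate 3 (0.392) than its own group (0.422 and 0.603).

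Splits of the 6 replicates of each comparison cannot give a share under 0.1, since there are 10. For LPS against untreated 1 split reached the real count of 6956 probes and the highest other gave 0; for PBD150 plus LPS against untreated 1 split reached 8061 and the highest other gave 0. For PBD150 plus LPS against LPS all 10 splits gave 0. At an unadjusted p under 0.05 the real split there had 1582 probes, and the split of LPS replicates 1 and 2 with PBD150 plus LPS replicate 3 had 5849, the highest of the 10, where the other 8 had 1003 to 2948. That split is the exchange of LPS replicate 3 with PBD150 plus LPS replicate 3, which gave the largest fall of the variance within groups (-24%). What makes these samples group in this way was not tested. In that comparison 5 splits had as many gene lists past the threshold as the real 4, and the highest other had 7; this test was chosen after seeing the data.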
